A study of Mus musculus with 3 samples.

How the data were processed

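Spatial transcriptomics arrays with poly(A) capture were used on 3 coronal sections of mouse main olfactory bulb, per the labels' protocols, and each section is 1 sample. The authors deposited, for each section, raw transcript counts per spot and gene for spots under tissue, and a table that gives every spot its array position, its pixel position and a named region. The counts are whole numbers with a different total in each section, and entries of 0 are not listed. Whether they count unique molecular identifiers, and which aligner, counter and annotation made them, is not given in the sources used here. The genome build was mm10, per the submitters' processing notes. Gene locations and biotypes were taken from the GENCODE M21 annotation of that build, in which 99.8% of 19621 gene symbols were found. How the regions were drawn, and whether gene expression was used to draw them, is not given in the sources used here.

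Spots were joined to regions by pixel position, which matched 100% of the entries of each section. By spot name, the files of sections 2 and 3 were offset from the region table, and 97.1% of their entries fell in the same region, so this join was an alternative. Counts without a gene name (112, 497 and 405 counts, or 0.0325%, 0.0764% and 0.0801%) and spots of unknown region stayed out of all tests. Counts were summed per section and region into 27 sums from 1456 to 182699 counts. Counts of each sum were scaled to a common total (CPM), and means and SDs are over the 3 sections. The totals of 344260, 650393 and 505305 counts limit the precision, most of all in the smaller regions.

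Before the data were examined, the tests, covariates, gene lists, alternatives and the rule for named genes were fixed. The main test was edgeR 4.0.16 (quasi-likelihood, R 4.3.3) on the sums, with region and section in the model, TMM scaling, and the filterByExpr filter by region with a minimum count of 10, which left 1996 genes. Each region was compared with the unweighted mean of the other 8, and each of 8 pairs of neighbouring regions directly, with Benjamini-Hochberg adjustment within a comparison and a threshold of 0.05. The pairs between the internal granule cell layer, the ependymal cell zone and the rostral migratory system were set from which regions touch, since the ependymal cell zone was not in the order fixed beforehand. The sums of a section share its tissue and array, and their deviations from region means correlated at 0.38 on average within a section (lowest 0.0319, 108 pairs) and at -0.167 across sections. A fitted log2 fold change depends on the prior count where a region has no counts, so CPM means, SDs and ratios of means are printed for named genes.

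Named genes were the 4 with the largest positive fold change in each region among those past the threshold, above the mean of the other regions in each section and with at least 30 counts in the region. For each pair of neighbours the 2 largest in each direction were named under the same conditions, and 2 to 4 members were named of each list described, led by those with the most counts, together with members that passed. Some genes that this rule takes are not reported here. Lars2 and the genes named in the closing observations outside this rule were chosen after their values were seen. Of 21 gene lists of cell types and gene groups, the 12 with at least 3 tested genes were tested against the other tested genes with camera (limma 3.58.1) at a preset correlation of 0.01 and again with an estimated one, adjusted over 108 list and region pairs. The others are given as CPM, except the mitochondrially encoded list, of which the files held 0 genes.

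The pipeline was tested on simulated counts for the 1996 genes, with 200 genes changed by a fold of 2 or 4 in a single region. All other genes had the same share in every region of a section, and each gene's spread was that of the fitted trend. Real layers differ in more ways, so recovery in the real data may be lower. A fold of 4 was recovered for between 97% and 100% of changed genes against the other regions, except in the rostral migratory system (57%), where 13.2% of the calls were false. Genes at least 95% identical over at least 100 bases to a mitochondrial transcript were found with blastn 2.17.0, which gave 11 genes. Counts per spot were compared by permuting region labels within sections with 100000 resamples (Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1), and figures were drawn with matplotlib 3.10.9.

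The alternatives were RLE scaling, no filter on low counts, no section block, each section left out, spots within 5 array positions of another region left out, DESeq2 1.42.0, an estimated correlation, a pseudocount of 10 CPM, a minimum of 10 counts, annotated spots alone and spots without counts included. After the data were seen, scaling by library sizes alone, a fit without the rostral migratory system, a fit without its sum in section 3, a fit without a set of mitochondria-like and miRNA genes, the join by spot name and a fit of the 5 regions that the fit without boundary spots could use, with those spots kept, were added. That set held the 11 genes found with blastn, all genes of miRNA biotype, Lars2 and Gm15564. Resemblance to ribosomal RNA was not measured. An alternative without mitochondrially encoded genes, fixed beforehand, could not be run because the files held 0 genes with that prefix. For the alternative without boundary spots, sums under 5000 counts were left out, a limit set after smaller sums had made the fits unstable, which left 5 regions.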

Results

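Poly(A) RNA was captured on high-density spot arrays from 3 coronal sections of mouse main olfactory bulb (strain C57BL/6J, 12 weeks of age), the first relay of the sense of smell. The authors' files placed nearly every spot under tissue in 1 of 9 nested regions, and the rest in none. From outside to inside these were the olfactory nerve layer (ONL), the glomerular layer (GL), the external plexiform layer (EPL), the mitral layer (M/T), the internal plexiform layer (IPL), the external and internal granule cell layers (GCL-E and GCL-I), the ependymal cell zone (E) and the rostral migratory system (RMS), in the names of the deposited annotation. The labels do not say which animal each section came from, and counts of Y-linked genes and Xist argue against a single animal for all 3 (closing observations). Differences between whole sections were taken out as a block, so p-values measure only the remaining spread of the sums of these 3 sections. Sections 1, 2 and 3 held 344260, 650393 and 505305 transcript counts on 113420, 158033 and 146283 spots with at least 1 count. A spot with counts held 3.04, 4.12 and 3.45 counts on average, so single spots were not compared, and counts were summed per section and region.

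**Figure D1:**
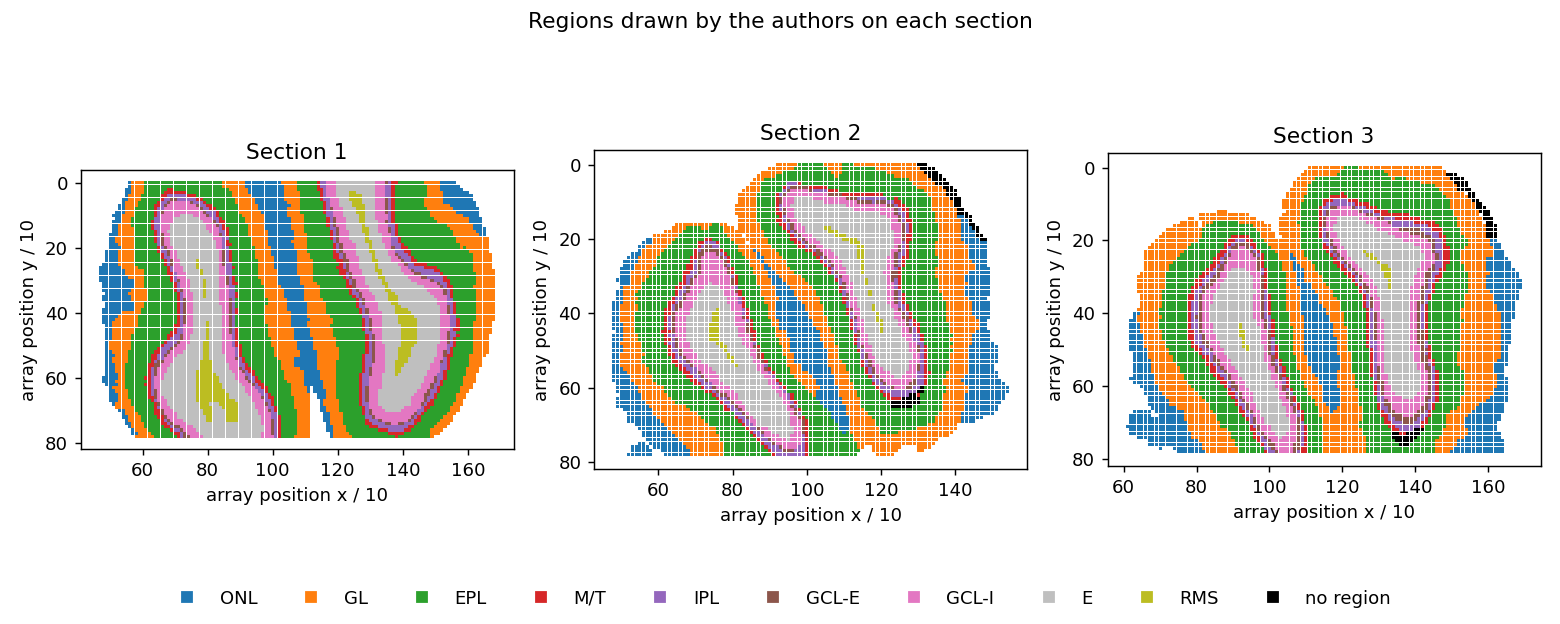
Map of the authors' regions on the 3 sections, with both axes in array positions divided by 10 and each square coloured by the region of its spots (black, no region). The 9 regions lie nested in each bulb, with the rostral migratory system innermost.

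The deposited counts were unevenly spread over the layers. On average the external plexiform layer held the most counts, 24.8% ± 3.61 (SD, n = 3) of those in annotated regions, and the rostral migratory system the fewest, 1.94 ± 2.43%. The ependymal cell zone held the most in section 1 (25.6%) and the glomerular layer in section 3 (26.3%). Per 100 spots, the mitral layer, which holds the cell bodies of the output neurons, gave 91.0 ± 43.3 counts, the external plexiform layer 60.9 ± 30.8 and the olfactory nerve layer 58.7 ± 34.6. The internal plexiform, external granule and internal granule cell layers gave 83.3 ± 28.2, 83.6 ± 29.3 and 81.8 ± 25.4. In section 1 the mitral layer (44.8) was below these layers (54.9, 52.3 and 57.4 in the same order). Relative to its section's mean over regions, the mean log2 count of a spot with counts was 0.23 ± 0.18 in the mitral layer and -0.28 ± 0.06 in the olfactory nerve layer. The variance between regions of this measure was 0.0249 (two-sided permutation test within sections, 100000 resamples, p = 0.00181). With spots without counts included the permutation p was 0.0575, and without sections 1, 2 and 3 in turn it was 6e-05, 0.116 and 0.0778. The rostral migratory system summed to 16285, 5162 and 1456 counts in sections 1, 2 and 3, which limited every comparison that involved it.

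Section 1 stood apart from the others. Across genes, which are not independent replicates, log2(CPM + 1) correlated with Pearson r = 0.803 between sections 1 and 2, 0.791 between sections 1 and 3 and 0.909 between sections 2 and 3 (Spearman rho 0.822, 0.821 and 0.928). A library deposited again would differ by counting noise alone, and each pair differed by more, with a chi-square of 114613 on 10911 degrees of freedom, 96758 on 10351 degrees of freedom and 13569 on 11293 degrees of freedom in the same order. Counts on Lars2, annotated as a mitochondrial leucyl-tRNA synthetase gene, took 0.00639% of section 1 and 1.99% and 1.61% of sections 2 and 3. Whether these counts came from the mRNA of that gene was not tested. The 11 genes resembling mitochondrial transcripts were also lower in section 1, at 1.86045% against 6.28546% and 6.6031%. So were genes of miRNA biotype, at 0.174% against 0.825% and 0.792%. Section was kept as a block in every region test.

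The comparison of each layer with the unweighted mean of the other 8 asked which transcripts marked it. The naming rule took only genes that were higher in the region in 3 of 3 sections, so that agreement is no separate support. In section 1 it rested on 1 count for Slc7a11 and for Itgb8 and on 3 for Scd1. In the olfactory nerve layer, where sensory axons and the glia that wrap them enter the bulb, 133 of 1996 genes differed, 119 higher and 14 lower. Omp, the olfactory marker protein of mature sensory neurons (chromosome 7, 98143359 to 98145502, mm10), measured 423 ± 172 CPM (SD, n = 3) against 50.8 ± 12.9 CPM, a ratio of means of 8.33, adjusted p = 9.45e-20. S100a5, a calcium-binding protein gene of the same neurons, measured 653 ± 143 against 98.2 ± 21.7 CPM (adjusted p = 1.85e-23). Scd1, a fatty acid desaturase gene (chromosome 19, 44394455 to 44407879), measured 1159 ± 838 against 177 ± 34.5 CPM (adjusted p = 4.91e-54). It stood at 193 CPM, on 3 counts, in section 1 and at 1698 and 1584 CPM in sections 2 and 3. Slc7a11, a cystine transporter gene, measured 278 ± 189 against 73.6 ± 62.5 CPM (adjusted p = 3.63e-12). All 3 tested genes of the olfactory sensory axon list rose, as did all 4 of the olfactory ensheathing glia list, and both lists passed camera (adjusted p = 1.29e-12 and 5.14e-19). Apod and Fabp7 of the glial list stood at 1937 ± 432 CPM and 1854 ± 676 CPM there. Genes of other lists rose as well. Ptgds, 1 of 2 tested meningeal fibroblast genes, stood at 4092 ± 471 CPM, and Vtn, 1 of 2 tested endothelial and mural genes, at 419 ± 44.4 CPM. Of 10 astrocyte genes 5 rose (adjusted p = 0.0102, or 0.145 with an estimated correlation). Of the 4 tested blood genes 3 rose (adjusted p = 2.62e-08), with Hbb-bs, a haemoglobin chain, at 1193 ± 308 CPM. The synaptic vesicle list was lower (adjusted p = 1.05e-04), and 1 of its 10 members, Snap25, fell. With library sizes as the only scaling, 83 genes were higher and 61 lower, and without the rostral migratory system 120 and 36. The count was 53 without section 2, 87 without section 3 and 29 without the section block.

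The glomerular layer, in which sensory axons meet their target neurons, differed in 218 genes, 175 higher and 43 lower. Eomes, a transcription factor of glutamatergic projection neurons (chromosome 9, 118478212 to 118486132), measured 259.6 ± 37.7 CPM against 85.7 ± 17.4 CPM, a ratio of means of 3.03, adjusted p = 3.93e-09. Gng13, a G-protein subunit gene of sensory neurons, measured 220.4 ± 46.4 against 87.1 ± 14.7 CPM (adjusted p = 4.45e-07), and Omp measured 156 ± 65.0 against 84.1 ± 25.6 CPM (adjusted p = 1.07e-05). Nxph1, which encodes a secreted ligand of neurexins, measured 211 ± 51.0 against 75.3 ± 55.0 CPM (adjusted p = 6.61e-08). The olfactory sensory axon list rose in all 3 tested members (adjusted p = 4.05e-06), the ensheathing glia list in 3 of 4 (8.02e-05) and the mitral and tufted cell list in 5 of 8, or 6 of 8 adjusted over the list alone (1.98e-08). Of 10 astrocyte genes 6 rose (adjusted p = 4.22e-06), as did 3 of 4 tested blood genes (adjusted p = 0.00112, or 0.0795 with an estimated correlation). Ptgds rose there too, at 1177 ± 332 CPM. Of the granule cell list, Camk2a, Pcp4 and Tshz1 fell and Gad2 rose (adjusted p = 4.88e-05, direction down). With library sizes as the only scaling, 97 genes were higher and 86 lower, and without the rostral migratory system 143 and 94. The count was 56 without section 2, 96 without section 3, 13 without the block and 124 with DESeq2.

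The external plexiform layer, a zone of dendrites, differed in 242 genes, 215 higher and 27 lower. Doc2g, a gene of mitral and tufted cells (chromosome 19, 4003313 to 4007005), measured 940.0 ± 396 CPM against 339 ± 164 CPM, a ratio of means of 2.77, adjusted p = 2.95e-27. Paqr8, a membrane progestin receptor gene, measured 352 ± 235 against 138 ± 74.5 CPM (adjusted p = 5.34e-11), and Sept3, a septin gene of neurons, 266 ± 159.6 against 135 ± 72.7 CPM (adjusted p = 1.43e-06). Gm13339, an unprocessed pseudogene (chromosome 2, 22590024 to 22590533) that is 96.7% identical to the mitochondrial transcript mt-Nd2 over 510 bases, measured 708 ± 534 against 370.1 ± 249.7 CPM (adjusted p = 1.96e-11). Whether its counts came from the pseudogene or from the mitochondrial transcript was not tested. Of 10 astrocyte genes 9 rose (adjusted p = 5.83e-15), among them Slc1a2, a glutamate transporter gene, at 2968 ± 2091 CPM against 1207 ± 774 CPM in the internal granule cell layer, Sparcl1, a secreted glycoprotein gene, at 2567 ± 688 CPM against 1221 ± 155 CPM, and Glul, glutamine synthetase, at 2702 ± 653 CPM against 1245 ± 239 CPM. Slc1a2 in this layer stood at 578 CPM in section 1 and at 4455 and 3871 CPM in sections 2 and 3. Of 8 mitral and tufted cell genes 6 rose, and 8 adjusted over the list alone (adjusted p = 1.78e-13). The blood list was higher as well (adjusted p = 0.00112, but 0.0890 with an estimated correlation). With library sizes as the only scaling, 120 genes were higher and 74 lower. The count was 101 without section 2, 116 without section 3, 4 without the block, 133 with DESeq2 and 839 without the filter on low counts.

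The mitral layer differed in 44 genes, 38 higher and 6 lower. Rab3b, a synaptic vesicle GTPase gene (chromosome 4, 108879063 to 108943324), measured 547 ± 67.1 CPM against 167 ± 45.0 CPM, a ratio of means of 3.28, adjusted p = 1.36e-07. Gap43, a growth cone protein gene, measured 408 ± 98.0 against 129 ± 68.4 CPM (adjusted p = 7.83e-05), Doc2g 911 ± 477 against 343 ± 153 CPM (adjusted p = 1.36e-07) and Trnp1, a nuclear protein gene, 409.9 ± 195 against 187 ± 90.6 CPM (adjusted p = 0.00801). Of 8 mitral and tufted cell genes 7 rose (adjusted p = 2.80e-15), with Slc17a7, a vesicular glutamate transporter gene, at 985 ± 429 CPM against 191 ± 42.5 CPM in the internal granule cell layer. The synaptic vesicle list was higher (adjusted p = 3.70e-06), and Snap25 and Syt1 rose. The myelinating oligodendrocyte list was lower (adjusted p = 9.10e-07), and Mobp was among the members that fell. The ribosomal protein list was lower (adjusted p = 1.52e-07) although 0 of its 73 genes passed alone. The adjusted p of Trnp1 was 0.0936, 0.0528 and 0.111 without sections 1, 2 and 3 and 0.136 without the rostral migratory system, and the count was 16 without section 2, 22 without section 3 and 2 without the block.

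No gene passed in the internal plexiform layer with edgeR (0 of 1996, and 140 at an unadjusted p under 0.05) or with DESeq2 (0), and 2 passed without section 1. In simulated data, in which no other region differed, a fold of 4 in this layer was recovered for 100% of changed genes and a fold of 2 for 57%. The external granule cell layer differed in 8 genes, 3 higher and 5 lower. Egr1, an immediate early gene whose product is a transcription factor (chromosome 18, 34859823 to 34864984), measured 1088 ± 655 CPM against 487 ± 338 CPM, a ratio of means of 2.24, adjusted p = 0.0208. Its adjusted p was 0.343 without section 2 and 0.258 without section 3, and 0.0585 with spots joined by name, while 0 genes passed without section 2, without section 3 or without the block. With library sizes as the only scaling 13 genes were higher and 9 lower, with RLE scaling 10 and 5, with DESeq2 13 and 6, without the rostral migratory system 5 and 16, and without the filter on low counts 0 and 11. With region labels exchanged at random within sections, 8 of 100 groupings (the real one included) gave at least as many genes. The granule cell list was higher there (adjusted p = 2.65e-04), with 3 of 10 genes passing adjusted over the list alone and 0 over all genes.

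The internal granule cell layer, packed with inhibitory interneurons, differed in 66 genes, 48 higher and 18 lower. Ptk2b, a tyrosine kinase gene (chromosome 14, 66153257 to 66281052), measured 464 ± 59.4 CPM against 211 ± 88.0 CPM, a ratio of means of 2.19, adjusted p = 1.80e-04. Icam5, an adhesion molecule gene of forebrain neurons, measured 527 ± 143 against 252 ± 98.7 CPM (adjusted p = 2.09e-04), R3hdm4 277 ± 82.4 against 133 ± 57.3 CPM (adjusted p = 0.0213) and Emsy 195 ± 104 against 75.2 ± 24.0 CPM (adjusted p = 0.0177). Of 10 granule cell genes 4 rose, and 8 adjusted over the list alone (adjusted p = 3.12e-10). Gad1, a GABA synthesis enzyme gene, stood at 3076 ± 709.7 CPM against 1358 ± 542 CPM in the external plexiform layer, and Pcp4, a calmodulin-binding protein gene, at 1816 ± 434 CPM against 680.1 ± 412 CPM. The immediate early list was higher (adjusted p = 5.15e-04), and Egr1 was its member that rose. Syn1, Syn2 and Vamp2 of the synaptic vesicle list rose (adjusted p = 1.93e-05). The adjusted p of Ptk2b was 0.0608 without section 2, that of Icam5 0.0761 without section 3, and that of R3hdm4 0.0765, 0.386 and 0.0761 without sections 1, 2 and 3. The count was 8 without section 2, 17 without section 3 and 0 without the block. Without the rostral migratory system 58 genes were higher and 50 lower, and with RLE scaling 47 and 30. With 5 regions alone 148 were higher and 138 lower, and with boundary spots left out as well 39 and 67.

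In the ependymal cell zone 52 genes differed, 43 higher and 9 lower. Bcl11b, a transcription factor gene (chromosome 12, 107910403 to 108003602), measured 281 ± 91.6 CPM against 131 ± 54.2 CPM, a ratio of means of 2.13, adjusted p = 0.00433. Cx3cl1, a chemokine gene of neurons, measured 228 ± 87.5 against 116 ± 10.7 CPM (adjusted p = 0.0113), Otub1, a deubiquitinase gene, 215 ± 91.9 against 101 ± 57.1 CPM (adjusted p = 0.0184) and Tjp1, a tight junction protein gene, 179 ± 63.6 against 96.3 ± 60.1 CPM (adjusted p = 0.0203). These 4 genes had 0 counts in 1 other region, as had Omp, Slc7a11, Eomes, Gng13, Paqr8, Gm13339, Sept3, Trnp1 and Emsy, named for other regions. Without the rostral migratory system the adjusted p was 0.0540 for Cx3cl1, 0.0891 for Otub1 and 0.0621 for Tjp1, with 52 genes higher and 45 lower. Without section 1 it was 0.259 for Cx3cl1, 0.114 for Tjp1 and 0.0547 for Bcl11b. Without section 2 it was 0.0637 for Otub1 and 0.0637 for Cx3cl1, and without section 3 it was 0.323, 0.0953 and 0.135 for Otub1, Tjp1 and Bcl11b. Of 10 granule cell genes 5 rose in this zone (Camk2a, Pbx3, Pcp4, Penk and Tshz1, list adjusted p = 1.58e-06). The myelinating oligodendrocyte list was higher with Mbp and Mobp rising (adjusted p = 0.00112, but 0.0877 with an estimated correlation). RLE scaling gave 22 genes higher and 23 lower, DESeq2 8 and 11, 5 regions alone 99 and 93, and these 5 without boundary spots 71 and 73, and the count was 9 without section 2, 12 without section 3 and 2 without the block.

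In the rostral migratory system, the path of migrating neuroblasts, 18 genes differed, 5 higher and 13 lower, against a median log2 fold change of all genes of -0.44. Mbp, myelin basic protein (chromosome 18, 82475146 to 82585637), measured 4855 ± 2531 CPM against 1348 ± 487 CPM, a ratio of means of 3.60, adjusted p = 7.74e-09. Cst3, a cysteine protease inhibitor gene, measured 6148 ± 1483 against 2406 ± 662 CPM (adjusted p = 6.16e-04). Without section 1 the adjusted p of Mbp was 0.422 and that of Cst3 0.624, and without section 2 that of Cst3 was 0.0949. The myelinating oligodendrocyte list was higher, with Mbp among the members that rose (adjusted p = 2.86e-10), and the synaptic vesicle list was lower, with Syt1 falling (adjusted p = 1.27e-05). The neuroblast list, with 6 of its 11 genes tested, did not pass (adjusted p = 0.906). Library sizes as the only scaling gave 9 genes higher and 1 lower, RLE scaling 5 and 3, and the sums without that of section 3 gave 5 and 4. Without the filter on low counts 1 gene was higher and 43 lower, and without section 1 the split was 0 and 11. With region labels exchanged at random within sections, 5 of 100 groupings (the real one included) gave at least as many genes. The count was 11, 3 and 9 without sections 1, 2 and 3 and 1 without the block, and in simulated data a fold of 4 here was recovered for 57% of changed genes.

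**Figure D2:**
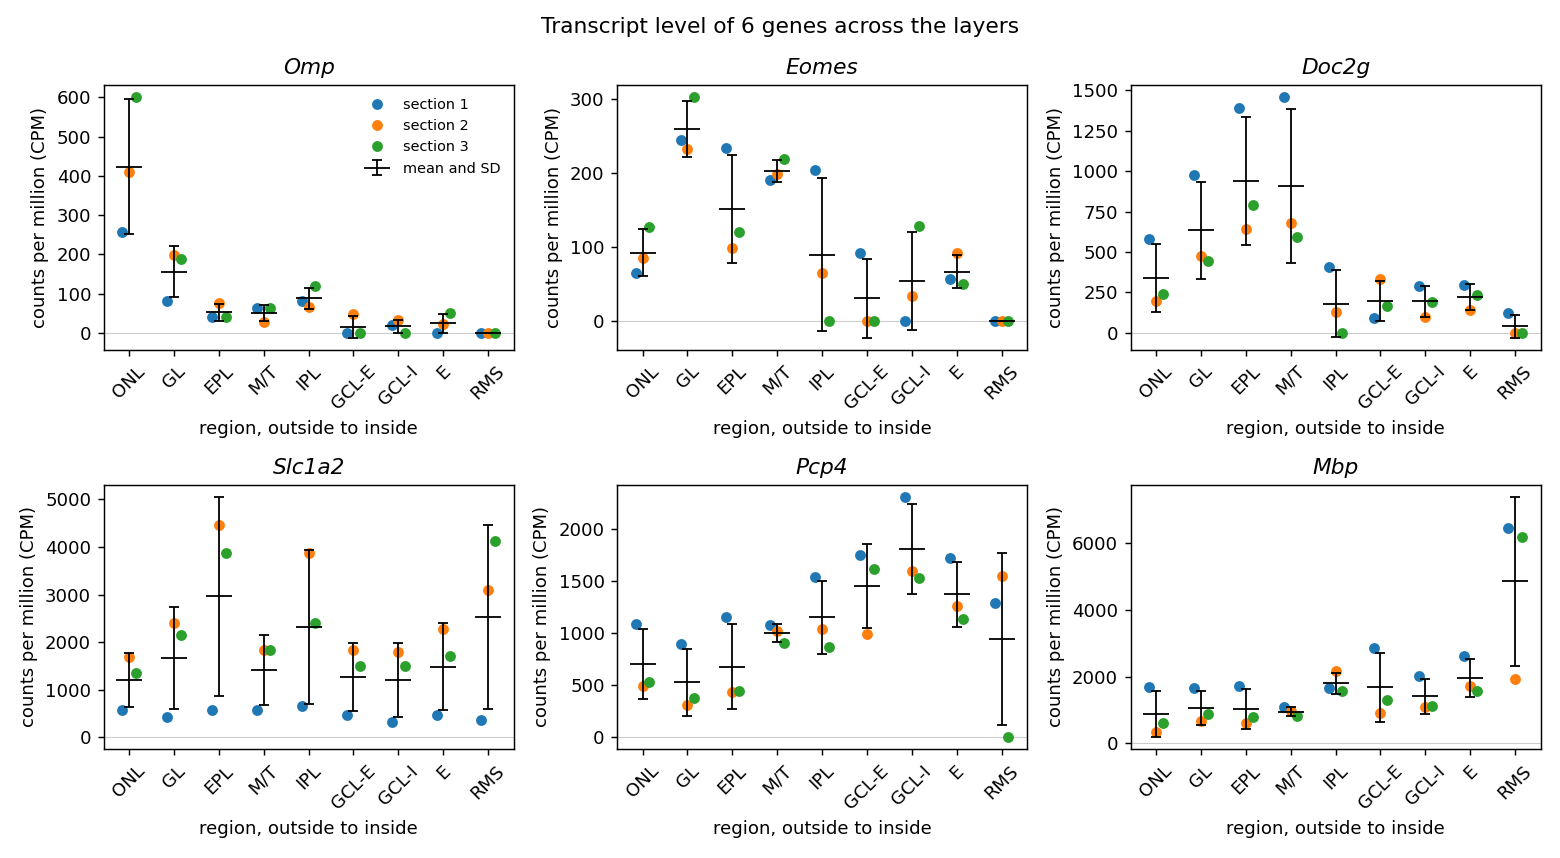
CPM of 6 genes in the 9 regions from outside to inside, with a point per section and the mean and SD of the 3 sections in black. Mean Omp was highest in the olfactory nerve layer and mean Mbp in the rostral migratory system, although Mbp in section 2 was higher in the internal plexiform layer (2153 against 1937 CPM), and Slc1a2 was lower in section 1 than in sections 2 and 3 in each region.

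Across the 12 lists that held at least 3 tested genes, 50 of 108 list and region pairs passed camera with the preset correlation of 0.01, and 29 with an estimated correlation. With region labels exchanged at random within sections a median of 21 pairs passed with the preset correlation. The astrocyte list was lower in the external and internal granule cell layers (adjusted p = 1.04e-06 and 7.77e-06), where Slc1a3, a glutamate transporter gene, was the member that fell. It was higher in the glomerular layer (adjusted p = 4.22e-06) and, with the preset correlation alone, in the olfactory nerve layer (adjusted p = 0.0102, but 0.145 with an estimated correlation). The mitral and tufted cell list was lower in the ependymal cell zone, with Reln and Slc17a7 falling (adjusted p = 3.09e-07). In the internal granule cell layer it was lower with Cck and Slc17a7 falling (adjusted p = 2.38e-04, but 0.0518 with an estimated correlation). The ribosomal protein list was higher in the ependymal cell zone (adjusted p = 0.00346, but 0.171 with an estimated correlation). In the rostral migratory system it passed upward (adjusted p = 0.00361, but 0.207 with an estimated correlation) while its median log2 fold change was 0.03 and its mean -0.11.

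**Figure D3:**
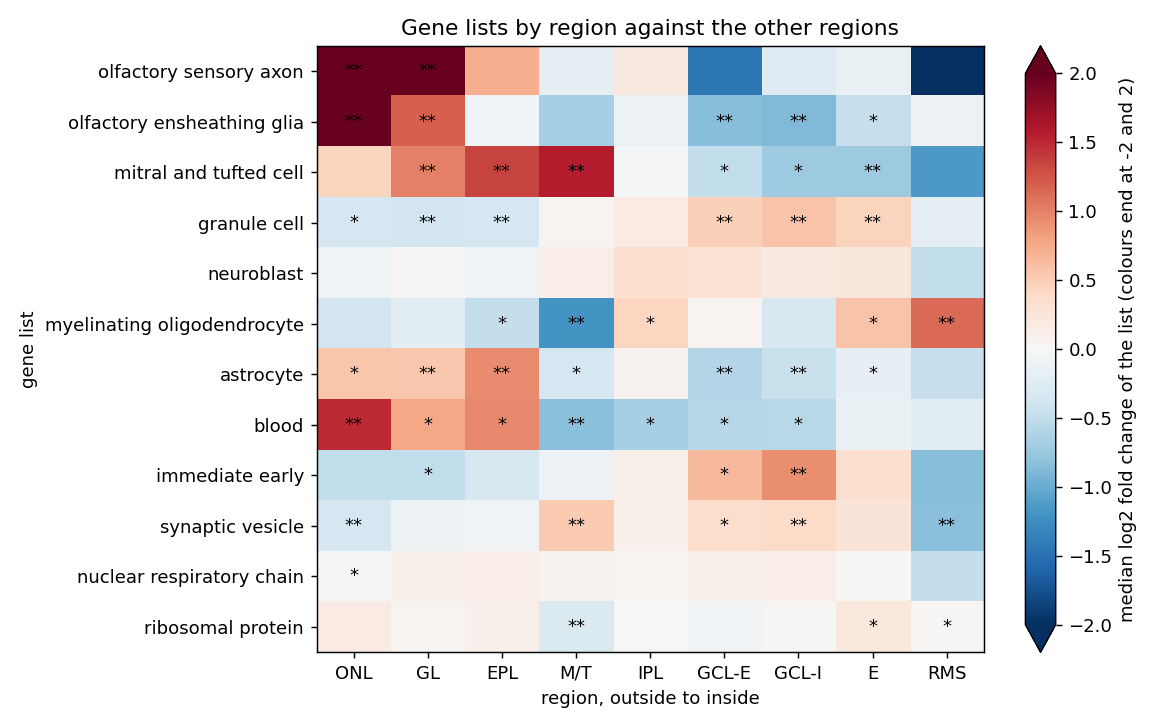
Median log2 fold change of 12 gene lists (rows) in each region against the other regions (columns). One star marks an adjusted p under 0.05 with the preset correlation and a pair of stars also with the estimated one, and 50 cells carry a star.

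Neighbouring regions were compared to look for changes at single layer borders. On average 97.3% of mitral, 90.9% of internal plexiform and 98.5% of external granule cell layer spots lay within 5 array positions of another region. Mixing across the borders of these 3 layers could therefore not be checked by leaving such spots out. Between the olfactory nerve and glomerular layers 38 genes differed, 32 higher in the nerve layer and 6 in the glomerular layer. Scd1 measured 1159 ± 838 against 297 ± 116 CPM (adjusted p = 5.81e-21), and Igfbp5, an insulin-like growth factor binding protein gene, 939 ± 536 against 263 ± 51.6 CPM (adjusted p = 6.22e-17). In section 1 the 2 layers stood at 193 and 163 CPM for Scd1, on 3 and 8 counts, and at 322 and 204 CPM for Igfbp5, against 1698 and 364 CPM for Scd1 in section 2. Higher in the glomerular layer were Inpp5f, a phosphoinositide phosphatase gene, at 182 ± 37.1 against 40.3 ± 35.2 CPM (adjusted p = 0.0131) and Shisa9, an AMPA receptor auxiliary protein gene, at 238 ± 46.9 against 55.9 ± 56.6 CPM (adjusted p = 0.0289). The adjusted p of Shisa9 was 0.0627 without section 1, and with DESeq2 it was 0.134 for Inpp5f and 0.150 for Shisa9. The count was 6 without section 2, 12 without section 3 and 0 without the block.

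Between the glomerular and external plexiform layers 32 genes differed, 17 higher in the glomerular layer and 15 in the plexiform layer. Npy, a neuropeptide gene, measured 209.8 ± 119 against 55.3 ± 27.6 CPM (adjusted p = 0.00309) and Kctd12, a GABA-B receptor subunit gene, 358 ± 241 against 116 ± 55.6 CPM (adjusted p = 4.00e-07). Camk2a, a calcium-dependent kinase gene, was higher in the plexiform layer, at 479 ± 255 against 169 ± 58.5 CPM (adjusted p = 7.93e-08), as was Jph4, a junctophilin gene, at 143 ± 30.6 against 49.4 ± 19.8 CPM (adjusted p = 0.0268). Without section 2 the adjusted p was 0.428 for Npy, 0.673 for Jph4 and 0.130 for Camk2a, and without section 1 it was 0.0592 for Npy. The count was 49, 3 and 9 without sections 1, 2 and 3 and 0 without the block. Without the rostral migratory system 18 genes were higher in the glomerular layer and 24 in the plexiform layer, and without section 1 the split was 19 and 30. With 5 regions alone it was 19 and 28, with boundary spots left out as well 13 and 31, and with DESeq2 7 and 3, with an adjusted p of 0.0959 for Jph4.

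Between the external plexiform and mitral layers 64 genes differed, 60 higher in the plexiform layer and 4 in the mitral layer. Itgb8, an integrin subunit gene, had 101 counts in the plexiform layer and 3 in the mitral layer, a ratio of rates of 7.35 (95% exact interval 2.44 to 36.2, counting error only), with an adjusted p of 4.67e-04. Prex1, a guanine nucleotide exchange factor gene, had 90 and 3 counts, a ratio of 6.55 (2.17 to 32.3), with an adjusted p of 0.00113. Scg2, a secretogranin gene, was higher in the mitral layer, at 731 ± 186 against 352 ± 59.9 CPM (adjusted p = 0.0307). Without section 2 the adjusted p was 0.446, 0.0778 and 0.586 for Itgb8, Prex1 and Scg2, and without section 3 it was 0.257 and 0.257 for Prex1 and Scg2. The count was 4 without section 2, 16 without section 3, 0 without the block and 41 without the set of mitochondria-like and miRNA genes. With library sizes as the only scaling 44 genes were higher in the plexiform layer and 31 in the mitral layer, with RLE scaling 50 and 13, and with DESeq2 31 and 20.

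Between the mitral and internal plexiform layers 4 genes differed. Doc2g was higher in the mitral layer, at 911 ± 477 against 179 ± 208 CPM (adjusted p = 4.75e-05), as was Cdhr1, a cadherin-related gene of mitral and tufted cells (chromosome 14, 37077857 to 37098347), at 731 ± 69.9 against 276 ± 290.1 CPM (adjusted p = 0.0201). Mobp, a myelin protein gene, was higher in the internal plexiform layer, at 650.0 ± 141 against 219 ± 162 CPM (adjusted p = 0.0146). The adjusted p of Cdhr1 and Mobp was 0.840 and 0.840 without section 2 and 0.598 and 0.155 without section 3. The count was 13, 1 and 1 without sections 1, 2 and 3 and 0 without the block. Without the rostral migratory system 6 genes were higher in the mitral layer and 5 in the internal plexiform layer, with RLE scaling 7 and 1, and with DESeq2 3 and 0, with an adjusted p of 0.0920 for Mobp. With edgeR 0 genes differed between the internal plexiform and external granule cell layers, between the granule cell layers, between the internal granule cell layer and the ependymal cell zone, or between that zone and the rostral migratory system, with 115, 71, 128 and 262 genes at an unadjusted p under 0.05. DESeq2 called 0, 0, 1 and 0 genes in the same order, edgeR without section 1 called 1, 0, 1 and 2, and without section 3 it called 1 gene for the outermost of these pairs. Without the filter on low counts 98 genes were called between the ependymal cell zone and the rostral migratory system, 98 higher in the zone and 0 lower, and with RLE scaling 3, while 3 were called between the internal granule cell layer and the zone without boundary spots. In simulated data a fold of 2 in the internal granule cell layer was recovered against its outer neighbour for 21% of changed genes and a fold of 4 for 97%, and against the ependymal cell zone for 52% and 100%. For a change in the external granule cell layer it was 19% and 88% against the internal one and 10% and 80% against the internal plexiform layer. Between the zone and the rostral migratory system it was 16% and 82% for a change in the zone. For a change in the rostral migratory system it was 4% and 48%, and 17.5% of the calls were false.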

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

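The measurement of spots that no region was given to was looked at because it lies outside every comparison. Such spots held 42 counts on 91 spots in section 1, 5699 counts on 6424 spots in section 2 and 3435 counts on 4444 spots in section 3, each above the floor of 3 counts used for this flag. Per 100 spots this was 46.2, 88.7 and 77.3 counts. No explanation was tested for them, and with 3 sections no section was tested as an outlier.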

How the results depend on the processing

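The fits with library sizes alone, without the rostral migratory system or its sum in section 3, without the set of mitochondria-like and miRNA genes, joined by spot name and with 5 regions alone were chosen after the data were seen, and those not named as such were planned. Layers are named by 1 or 2 words here, pairs from outside to inside, and each value is the number of genes that differed. The cause of the changes was not tested. The main values were 133 (nerve), 218 (glomerular), 242 (external plexiform), 44 (mitral), 0 (internal plexiform), 8 (external granule), 66 (internal granule), 52 (ependymal), 18 (migratory), 38 (nerve to glomerular), 32 (glomerular to external plexiform), 64 (external plexiform to mitral), 4 (mitral to internal plexiform), 0 (internal plexiform to external granule), 0 (external granule to internal granule), 0 (internal granule to ependymal), 0 (ependymal to migratory), 50 (list and region pairs). With RLE scaling those that moved were 15 (external granule), 8 (migratory), 8 (mitral to internal plexiform), 1 (internal granule to ependymal), 3 (ependymal to migratory). Without the filter on low counts those that moved were 212 (nerve), 647 (glomerular), 839 (external plexiform), 26 (mitral), 36 (internal granule), 145 (ependymal), 44 (migratory), 15 (nerve to glomerular), 12 (glomerular to external plexiform), 2 (mitral to internal plexiform), 1 (internal granule to ependymal), 98 (ependymal to migratory). Without the replicate block those that moved were 29 (nerve), 13 (glomerular), 4 (external plexiform), 2 (mitral), 0 (external granule), 0 (internal granule), 2 (ependymal), 1 (migratory), 0 (nerve to glomerular), 0 (glomerular to external plexiform), 0 (external plexiform to mitral), 0 (mitral to internal plexiform). Without boundary spots those that moved were 83 (nerve), 104 (glomerular), 151 (external plexiform), 106 (internal granule), 144 (ependymal), 3 (internal granule to ependymal), 32 (list and region pairs). With library sizes alone those that moved were 22 (external granule), 10 (migratory), 1 (internal plexiform to external granule), 2 (internal granule to ependymal), 3 (ependymal to migratory). Without the rostral migratory system those that moved were 21 (external granule), 108 (internal granule), 97 (ependymal), 11 (mitral to internal plexiform), 3 (internal plexiform to external granule), 2 (internal granule to ependymal). Without its sum in section 3 those that moved were 18 (external granule), 9 (migratory), 1 (internal plexiform to external granule), 2 (internal granule to ependymal), 1 (ependymal to migratory). Without the set of mitochondria-like and miRNA genes those that moved were 4 (external granule), 5 (migratory), 41 (external plexiform to mitral). With the 5 regions left without boundary spots, but those spots kept, those that moved were 128 (glomerular), 286 (internal granule), 192 (ependymal), 2 (internal granule to ependymal). Joined by spot name those that moved were 5 (external granule), 10 (mitral to internal plexiform). With DESeq2 those that moved were 124 (glomerular), 133 (external plexiform), 19 (external granule), 19 (ependymal), 20 (nerve to glomerular), 10 (glomerular to external plexiform), 1 (internal granule to ependymal). With an estimated correlation 29 list and region pairs passed. The 32 pairs without boundary spots were of 70 tested in 5 regions. Of these 70 pairs 60 were tested in the fit of all 9 regions, where 32 passed, and 24 passed in both fits. In the fit of 5 regions with boundary spots kept 41 of 70 passed. The fit without boundary spots also has fewer regions to compare with. With each section left out in turn the lowest and highest values were 53 and 188 (nerve), 56 and 203 (glomerular), 101 and 241 (external plexiform), 16 and 49 (mitral), 0 and 2 (internal plexiform), 0 and 12 (external granule), 8 and 72 (internal granule), 9 and 42 (ependymal), 3 and 11 (migratory), 6 and 45 (nerve to glomerular), 3 and 49 (glomerular to external plexiform), 4 and 89 (external plexiform to mitral), 1 and 13 (mitral to internal plexiform), 0 and 1 (internal plexiform to external granule), 0 and 0 (external granule to internal granule), 0 and 1 (internal granule to ependymal), 0 and 2 (ependymal to migratory), 43 and 46 (list and region pairs). Pearson r of sections 1 and 3 was 0.864 at a pseudocount of 10 CPM. Among genes with at least 10 counts in both sections r was 0.742 (sections 1 and 2), 0.757 (1 and 3) and 0.956 (2 and 3). The variance between regions of counts per spot was 0.0711 with spots without counts included (permutation p = 0.0575), and 0.022 to 0.0306 with each section left out. Of the values of named genes under the alternatives, 434 kept their direction and stayed past the threshold, 96 kept their direction without passing, and none reversed. The latter were 31 without the replicate block, 16, 12 and 9 without sections 2, 3 and 1, 11 without the filter, 2 joined by spot name, 3 with 5 regions alone and 4 each with DESeq2, without the rostral migratory system and without boundary spots. The adjusted p without the filter was 0.294 (Trnp1), 0.929 (Egr1), 0.0534 (R3hdm4), 0.636 (Cst3), 0.0605 (Shisa9), 0.0520 (Npy), 0.213 (Jph4), 0.887 (Scg2), 0.569 (Cdhr1), 0.569 (Mobp), without boundary spots it was 0.399 (Emsy), 0.278 (R3hdm4), 0.421 (Tjp1), 0.111 (Bcl11b), and with 5 regions alone 0.104 (Emsy), 0.0865 (Otub1), 0.532 (Tjp1). No value could be had without boundary spots for the mitral, internal plexiform, external granule and migratory regions, and the alternative without mitochondrially encoded genes was not run. Depth limited the rostral migratory system most, where a fold of 4 was recovered for 57% of simulated genes. The median log2 fold change of shared genes moved with library sizes alone by -0.21 (nerve), -0.15 (glomerular), -0.18 (external plexiform), 0.36 (migratory), -0.19 (external plexiform to mitral), -0.31 (ependymal to migratory) and with RLE scaling by -0.10 (ependymal), 0.14 (migratory), -0.12 (external plexiform to mitral), 0.10 (mitral to internal plexiform), -0.22 (ependymal to migratory).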

Other observations

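Chosen after the result was seen were the tests of another animal, of reads placed on nuclear copies, of an even background and of ependymal cells, and so were all counts over other groupings. The tests of GC content and length were set before their values were computed, but after genes that differed in section 1 had been listed. The tests of distance within the ependymal cell zone were set beforehand.

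The following lists held too few tested genes for a test across regions. The periglomerular interneuron list, of local neurons around the glomeruli, summed to 1523 ± 729 CPM (SD, n = 3) in the glomerular layer and 599.8 ± 258 CPM in the external plexiform layer. Its member Calb2, a calcium-binding protein gene, stood at 996 ± 469 CPM and 443 ± 147 CPM, with an adjusted p of 1.47e-16 for the glomerular layer against the other regions with edgeR. The meningeal fibroblast list summed to 4923 ± 251 CPM in the olfactory nerve layer and 1517 ± 396 CPM in the glomerular layer. Its member Ptgds, prostaglandin D synthase, had the lowest adjusted p of all genes in the nerve layer (3.63e-82), at 4092 ± 471 CPM against 1177 ± 332 CPM in the glomerular layer. The endothelial and mural list summed to 1992 ± 450.2 CPM in the nerve layer and 1199 ± 95.8 CPM in the glomerular layer.

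Cst3 held 157 of the 171 counts of the microglia list in the rostral migratory system, so that list gives the value of 1 gene there. It summed to 6435 ± 1925 CPM in the rostral migratory system and 3316 ± 875 CPM in the ependymal cell zone. The external plexiform interneuron list summed to 388 ± 82.1 CPM in its layer and 419.7 ± 119.9 CPM in the mitral layer. The proliferation and oligodendrocyte precursor lists summed to 231 ± 204 CPM and 317 ± 294 CPM in the rostral migratory system, on 7 and 9 counts. The neuroblast list, with 6 of its 11 genes tested, did not pass in any region, and its adjusted p in the rostral migratory system was 0.906. All its genes summed to 1742 ± 449 CPM there, on 33 counts, the highest mean of the 9 regions, and to 1648 ± 235 CPM in the mitral layer. Its tested members Stmn2 and Tubb3 rose in the mitral layer. The nuclear respiratory chain list was lower in the nerve layer (adjusted p = 0.0455, but 0.207 with an estimated correlation).

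Section 1 stood apart from sections 2 and 3. Across 1995 tested genes, the log2 ratio of section 1 over the mean of the others had a Spearman rho of 0.563 with transcript GC content and -0.566 with transcript length, against -0.131 and 0.229 for section 2 over section 3, so that GC content and length may account for part of the difference. The median of each of 5 by 5 bins of GC content and length was removed in each section, and the mean of a bin's medians over the 3 sections was added back. After this, rho between sections 1 and 2 rose from 0.432 to 0.638 and between sections 1 and 3 from 0.474 to 0.655, while that between sections 2 and 3 was 0.951. The term added back is the same in each section, and how much of the rise it makes was not tested. The remaining gap of 0.313 argues against these trends, as binned here, as the whole cause, and finer bins were not tested. Section 1 held 64 counts of Y-linked genes (Ddx3y, Eif2s3y, Kdm5d and Uty) and 0 of Xist. Sections 2 and 3 held 0 Y-linked counts and 11 and 9 of Xist. These counts argue against a single animal for all 3 sections. Whether the animal is the source of the difference stays open, since animal, array and library cannot be told apart with 1 such section.

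Counts placed on the 11 genes resembling mitochondrial transcripts, annotated as pseudogenes, took a larger share in the external plexiform layer than in the internal granule cell layer. The ratio was 1.91, 2.58 and 2.57 in sections 1, 2 and 3. Those of the 11 genes resembling mitochondrial transcripts that are unprocessed pseudogenes held 99.5% of the counts on unprocessed pseudogenes, and the files held 0 genes of the mitochondrial genome by name. Gm10925, the one with the most counts, was 100% identical to mt-Atp6 over all 678 of its bases. Its counts therefore cannot be told apart from those of that mitochondrial transcript. The share of 99.5% says what these counts resemble and does not bear on why the layers differ, so whether reads of mitochondrial transcripts placed on nuclear copies account for the difference stays open. Per 100 spots the ratio between the layers was 0.955 in section 1 and 2.15 and 2.06 in sections 2 and 3, so that an even background over the array stays open for section 1. No biological explanation was tested.

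The ependymal cell zone held granule neuron transcripts, and a candidate explanation is spread from the neighbouring granule cell layer. In zone spots more than 50 array positions from that layer the granule cell list summed to 8774 ± 474 CPM (SD, n = 3), and in zone spots within 10 positions to 9003 ± 259 CPM. The ratio of far to near was 0.976 ± 0.0807 (0.896, 0.975 and 1.06 in sections 1, 2 and 3), which argues against short-range spread. The far spots held 14103, 3872 and 2488 counts of all genes in the same order, so the ratios of sections 2 and 3 rest on few granule cell counts. The list is not specific to granule layers and stood at 5109 ± 944 CPM in the external plexiform layer. Spread beyond 50 positions was not tested. The ependymal list summed to at most 22.7 CPM in the zone, on 4 counts over the 3 sections, under a minimum of 10 counts that was set after these values were seen, so ependymal cells there stay open. No biological explanation was tested.

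Region labels were also exchanged within sections, in 99 random groupings beside the real one. As many genes as in the real grouping were found in 1 of 100 (the real one itself) for the olfactory nerve layer (133 genes, highest other 63), the glomerular layer (218 and 41), the external plexiform layer (242 and 60), the mitral layer (44 and 34) and the ependymal cell zone (52 and 37), and for the 50 list and region pairs (highest other 43). For the internal granule cell layer it was 2 of 100 (66 genes, highest other 113). The share was under 0.05 for each of these, with no adjustment for the number of counts judged. The lowest share that could be reached was 1 of 100. It was not under 0.05 for the external granule cell layer (8 of 100, 8 genes, highest other 42) or the rostral migratory system (5 of 100, 18 genes, highest other 79). For the internal plexiform layer (0 genes, highest other 48) any grouping has at least as many, so its 100 of 100 decides nothing. The median of the other groupings was 0 genes for each region and 21 list and region pairs. Single groupings called more genes than the real one for both granule cell layers, the internal plexiform layer and the rostral migratory system. The source of these high counts was not tested. For neighbouring pairs there are 4 groupings, too few for a share under 0.05. As many genes were found in 1 of 4 for the first 4 pairs from the outside (38, 32, 64 and 4 genes, highest other 13, 6, 40 and 1). For the inner 4 pairs it was 4 of 4, which their 0 genes each made certain (highest other 0, 1, 0 and 0).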
